A study of Mus musculus with 74 samples.

How the data were processed

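Single-cell CEL-Seq2 data of mouse bone marrow were used, a 3′ tag method with molecular identifiers, from C57BL/6J mice labelled Ebf1+/+ Prx1-Cre (control) or Ebf1 fl/fl Prx1-Cre (fl/fl below). The 74 libraries comprised 48 of stromal cells and 26 of haematopoietic progenitors. Per the labels, stromal donor 1 of each genotype gave separate CAR and PaS gate libraries sequenced in 2 runs, while the gate of stromal donors 2 to 4 was not given and these had 1 run. Progenitor libraries came from the HSC and the LSK gate. The label behind each donor number does not say whether it is 1 animal or a pool, so p-values measure the spread between these numbered donors.

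The deposited tables held expected counts per gene and cell barcode, which the authors had corrected for identifier collisions and had not scaled to depth. Inverting that correction with 4096 possible identifiers returned whole numbers in every table, with a largest deviation of 4.1e-12. The submitters' processing notes name bcl2fastq 2.17.1.14 and BWA 0.6.2-r126 and the builds mm10 and GRCm38; the counting tool and its annotation are not given in the sources used here. The tables list 28401 symbols, of which 82 are spike-ins and 28319 are genes. Positions came from GENCODE M21, matched by symbol for 327 of 331 named symbols.

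The tables hold 192 barcodes per library. A barcode entered as a cell with at least 1000 transcripts outside spike-ins, which kept 6266 of 14208 barcodes, 3145 stromal and 3121 progenitor. The labels state 96 cells per library, 1 cell was sorted per well of a 384-well plate, and no doublet caller was run. All 48 stromal libraries and 8 progenitor libraries had 96 filled barcodes, and 18 progenitor libraries had 128. Library totals ran from 126855 to 1810297 transcripts, and the median per cell of a library from 1736 to 11474. Intervals and limits given for counts cover counting error only.

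Cells were scaled to 5000 transcripts, log-transformed and clustered by the Leiden method at resolution 1 on 2000 variable genes, 30 principal components and 15 neighbours (scanpy 1.11.5, igraph 0.11.9, Python 3.11.15). Mitochondrial, ribosomal and predicted genes were left out of the clustering. A cluster took the name of a cell type when at least 3 of its markers exceeded a log2 fold of 1 against the other cells, with a pseudocount of 20 CPM, and at least 1 stood among its 10 leading genes. Other clusters stayed unnamed. Since the gate of stromal donors 2 to 4 is unknown, the stromal classes were rebuilt in this way and are written CAR-like and PaS-like.

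Expected counts were summed over the cells of a donor and class or gate and rounded after summing. Cells were not treated as replicates. A donor entered with at least 10 cells. The sums were compared with the edgeR quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on TMM-scaled counts after filterByExpr, with a Benjamini-Hochberg adjusted p under 0.05 as threshold. Both gates of a progenitor donor carry the same number, so donor was a block in the HSC against LSK comparison and in the interactions. Only 5 of the stromal donors had enough cells of both classes, so the stromal interaction rested on 10 sums. Values of single genes are TMM-scaled CPM with the SD between donors unless stated otherwise. Shares of cells were compared with a two-sided exact permutation test, with Benjamini-Hochberg adjustment over classes; 4 against 4 donors cannot go below p = 0.0286.

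Of 29 gene lists, those with at least 3 measured members were tested with camera (limma 3.58.1, voom weights) at a preset correlation of 0.01, with an estimated correlation and with fry beside it. The ribosomal list takes every symbol that starts with Rpl or Rps and a digit, and so also kinase genes such as Rps6kb1. The Schwann or muscle-like list had too few measured members in every comparison by genotype and between the HSC and LSK gates.

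The genes named below follow a rule. Ebf1 is given in every comparison that measured it. Where fewer than 5 genes passed a genotype comparison, or 0 an interaction, the 5 with the smallest p are named whatever their CPM, and are said not to pass; for HSC against LSK and the interactions, up to 8 each way among those that passed. From each list described, 2 to 4 members with the smallest p are named, and up to 6 of those that passed. Predicted genes and sex-linked genes were counted but not named by the rule. Gm42418 was named after its values were seen. The other rRNA-like and satellite-like genes of the progenitors were also examined then, and apart from mt-Rnr2 in the HSC gate they are not named, in part because several had log2 differences near 0 that changed sign between settings.

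Alternatives covered the size factors of DESeq2 in edgeR, DESeq2 1.42.0, limma-voom, no filter on low counts, cell minimums of 500 and 2000 transcripts, cells thinned to 1000 identifiers, whole identifier counts, each donor left out, the replicate number as a block and clustering at resolutions 0.5 and 2. The libraries of the progenitor donors fall into 2 inferred sets in which no index repeats, A (control 1 and 4, fl/fl 1, 4 and 5) and B (the rest), used as a covariate and separately. These sets are inferred from the index numbers, and the labels do not state them. In set A genotype went with library layout. Control donors 1 and 4 gave 2 libraries of 96 filled barcodes per gate. The fl/fl donors 1, 4 and 5 gave 1 library of 128 per gate, as did every donor of set B. Genotype and layout thus cannot be told apart within set A. Comparisons, lists, naming rule and these alternatives were fixed before the data were examined. Added afterwards were cells with at least 1000 genes, filled barcodes alone, sums without predicted genes, stromal donors 1 and 2 alone, the lists between HSC and LSK gates and within index sets, the replicate block with an estimated correlation, shares of named cells and shares within index sets, and leaving out donors in the HSC against LSK and interaction tests.

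Replicate numbers met the rule for pairing, every same-numbered correlation over 0.1, in 1 comparison. In the sums of all stroma, deviations of same-numbered donors of both genotypes correlated at 0.744, 0.591, 0.130 and 0.133 for numbers 1 to 4. Numbers 3 and 4 did not stand apart. Control donor 3 correlated with fl/fl donor 4 at 0.292, and control donor 4 with fl/fl donor 3 at 0.132. By the labels, both donors numbered 1 had separate gate libraries and 2 runs, and both numbered 2 had 8 libraries. The labels do not say whether a number shares a litter or day.

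The tests were checked on simulated data built from the same sums, with 200 of the genes changed, 100 of them 2-fold and 100 of them 4-fold. At these folds the test recovered 26 and 95 genes in CAR-like, 0 and 22 in PaS-like and 3 and 67 in all stroma. It recovered 93 and 100 genes in the HSC gate, 90 and 100 in the LSK gate, 99 and 100 between the gates, and 67 and 95 for the progenitor interaction. The stromal interaction test recovered 7 and 43. Unchanged genes called ran from 1 to 18 per comparison. A list with its members changed 2-fold was found by camera in every comparison with lists, but not in PaS-like cells once the correlation was estimated. Unchanged lists called with the preset correlation numbered 2 in the LSK gate and 1 between the gates, and 0 with an estimated correlation. Simulated genes were drawn independently, so the check does not cover lists whose members vary together.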

Results

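Single-cell transcripts of bone marrow were counted in mice whose Prx1-Cre, active in limb mesenchyme, met either wild-type or loxP-flanked (fl/fl) alleles of Ebf1, a transcription factor of the B lineage and of stroma. Stromal cells came from 4 control and 4 fl/fl donors, and HSC and LSK gate cells from 5 control and 6 fl/fl donors. CAR gate cells are PDGFRα+ Sca1- stromal cells and PaS gate cells their Sca1+ counterparts; LSK cells are lineage-negative, Sca1+ c-kit+ progenitors, and the HSC gate is their CD150+ CD48- CD135- part. Library totals were 126855 to 752896 transcripts in stroma and 640507 to 1810297 in progenitors. Per donor, the summed cells held 172386 to 1544572 transcripts for CAR-like, 67351 to 1309823 for PaS-like, 574712 to 1770692 for HSC gate and 1060696 to 2242711 for LSK gate cells. Each question below follows from the series title, which concerns the effect of mutant stroma on stem cells. The fl/fl libraries are named by their label, since Ebf1 was not lower in them.

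Ebf1 (chromosome 11, 44617317 to 45008091, plus strand, mm10) was the targeted gene and was read first. In CAR-like cells it stood at 1213 ± 73.0 CPM (SD, n = 4) in fl/fl and 1116 ± 162 CPM (n = 4) in control donors. In PaS-like cells it stood at 1174 ± 84.8 CPM (n = 2) in fl/fl and 590 ± 112 CPM (n = 3) in control donors, higher in 2 of 2 fl/fl donors. Without scaling, the CAR-like CPM by donor were 1239, 1237, 1121 and 1154 in fl/fl and 950, 984, 1155 and 1022 in control; the PaS-like CPM were 1169 and 1090 in fl/fl and 628, 540 and 505 in control. All stroma gave 820, 887.6, 591 and 514 CPM in fl/fl and 465, 761, 457 and 497 CPM in control. The edgeR log2 differences were 0.12 (SE 0.154) in CAR-like, 0.98 (SE 0.289) in PaS-like and 0.16 (SE 0.196) in all stroma, each with an adjusted p of 1, and the difference between both classes was -0.76 (SE 0.383, adjusted p = 1). In PaS-like cells the unadjusted edgeR p of Ebf1 was under 0.05, as for 87 of 7871 genes there. A 3′ tag outside the deleted part of a gene does not report its loss, and the labels do not give the deleted exons. Progenitors carried almost no Ebf1: 7 transcripts in fl/fl and 9 in control HSC gate cells, and 4 in fl/fl and 16 in control LSK gate cells, 14 of these in control donor 4, too few to test.

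**Figure D1:**
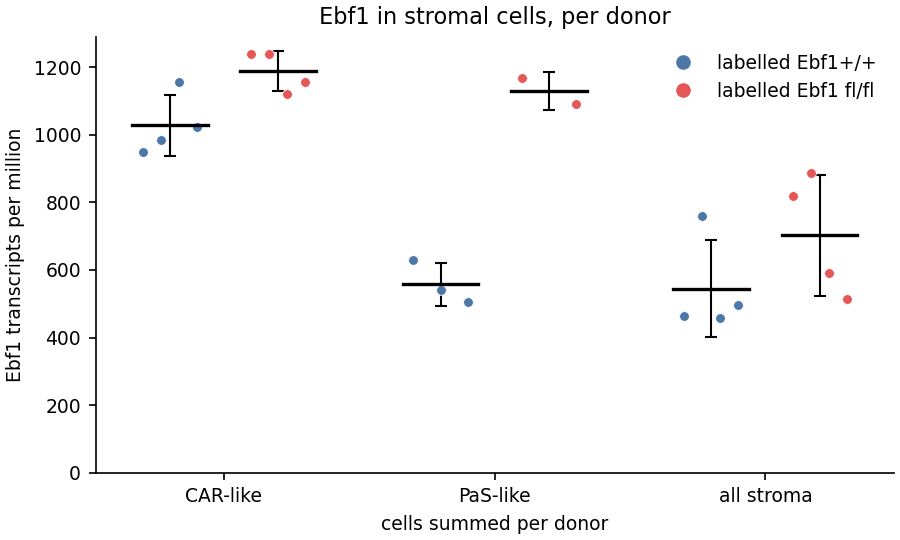
Ebf1 CPM (y axis, without scaling) in the cells of each class summed per donor (x axis); points are donors, black lines means and bars SD. The fl/fl donors lie between 1121 and 1239 in CAR-like cells and the control donors between 950 and 1155.

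The labelled CAR and PaS gates of donor 1 show what separates both stromal populations. The CAR gate was richer in Kitl, the stem cell factor gene, with 668 CPM against 102 CPM in the PaS gate of the control donor and 847 against 106 CPM in the fl/fl donor. Col11a2, a collagen gene of bone and cartilage, stood at 188 against 9.34 CPM and at 120 against 2.00 CPM, Cbln1 at 120 against 14.8 CPM and 160 against 10.4 CPM, and Pappa, a protease of IGF-binding proteins, at 453 against 67.4 CPM and 505 against 61.6 CPM. The other CAR gate genes named by the rule were Slc26a7, Cnnm1, Car3 and Vdr, the vitamin D receptor gene. In the PaS gate, Dpt, a dermal matrix protein gene, reached 623 CPM against 0.372 CPM in the control donor and 1204 against 0.426 CPM in the fl/fl donor. Tnxb, a tenascin gene, reached 261 and 411 CPM against 0.372 and 1.28 CPM, and Thy1 reached 250 and 324 CPM against 2.23 and 2.56 CPM. Clec3b reached 222 and 454 CPM against 0.372 and 0 CPM, Pi16 166 and 265 CPM against 0 and 0.852 CPM, and the eotaxin gene Ccl11 114 and 170 CPM against 0 in both; a count of 0 allows up to 1.12 CPM in the control and 1.28 CPM in the fl/fl CAR gate. Ly6a encodes Sca1 and so marks the gate itself. Ly6c1, at 526 and 907 CPM in the PaS gate, is a separate Ly6 gene, also on chromosome 15.

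By size alone, 165 genes were higher in the CAR gate and 213 in the PaS gate in both donors, by at least 2-fold. Of the CAR-like list, 17 of 18 members measured at 50 CPM or more were higher in the CAR gate, among them Cxcl12, the main homing chemokine of the marrow, at 12000 against 2950 CPM in the control donor and 15337 against 3100 CPM in the fl/fl donor, and Lepr at 989 against 292 CPM and 1382 against 202 CPM. Of the PaS-like list 17 of 17 were higher in the PaS gate, of the niche factors 10 of 18 in the CAR gate and 1 in the PaS gate, of the adipogenic genes 6 of 8 in the CAR gate and 1 in the PaS gate, of the osteoblast-like genes 8 of 14 and of the osteogenic genes 7 of 16 in the CAR gate, and of the extracellular matrix list 2 of 27 in the CAR gate and 6 in the PaS gate. Of the chondrocyte-like list, 4 of 6 were higher in the PaS gate, among them Prg4, the gene of the joint lubricant, at 3899 against 798 CPM in the control and 629 against 76.2 CPM in the fl/fl donor. Of the blood cell-like list 3 of 10 were higher in the CAR gate. Among cells with a named class, 77.5% of the control and 76.2% of the fl/fl CAR gate were CAR-like, and 60.9% and 76.3% of the PaS gate were PaS-like. Over all cells of the gate, 40.2% and 53.5% of the CAR gate were CAR-like and 33.9% and 41.8% of the PaS gate PaS-like. The gates were compared by size alone, without a test.

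In CAR-like cells, fl/fl and control donors were compared to ask what the genotype did to this population, and no gene passed. The genes with the smallest p were C2, a complement component (chromosome 17, 34862604 to 34898265, minus strand), at 46.1 ± 15.2 CPM in fl/fl and 119 ± 41.2 CPM in control donors (SD, n = 4 each; log2 difference -1.35, SE 0.317), and Igfbp3, which binds insulin-like growth factors (chromosome 11, 7206086 to 7213923, minus strand), at 92.5 ± 15.6 and 173 ± 51.4 CPM (log2 -0.92, SE 0.238). Ube4a, a ubiquitin ligase gene, stood at 19.2 ± 7.53 and 48.5 ± 9.77 CPM (log2 -1.09, SE 0.289). Tusc5, linked to glucose transporter traffic in fat, stood at 63.1 ± 33.7 CPM in fl/fl and 24.5 ± 6.87 CPM in control (log2 1.33, SE 0.369), and Wisp1, a matrix signalling gene, at 30.9 ± 12 and 11.6 ± 6.48 CPM (log2 1.39, SE 0.391). Each of these 5 had its direction in 4 of 4 fl/fl donors, with an adjusted p of 1. Of 7586 genes, edgeR called 0, with 143 at an unadjusted p under 0.05; DESeq2 and limma-voom also called 0. Of 24 lists, 2 passed camera with the preset correlation. The interferon response list was lower in fl/fl donors (adjusted p = 0.0332), with 18 of its 23 members below 0, such as Igtp (log2 -0.68, SE 0.317) and Ifi44 (-0.54, SE 0.283), and the oxidative phosphorylation list was higher (adjusted p = 0.0376), with 16 of 30 members above 0, such as Atp5j (0.30, SE 0.157) and Ndufb3 (0.42, SE 0.244). With an estimated correlation the adjusted p of each was 0.837, and with fry 0.914; no member of either passed over all genes, and none when adjusted over the list alone. The CAR-like list (adjusted p = 0.199, 5 of 18 members above 0), the niche factors (0.216) and the adipogenic (0.857), osteogenic (0.993) and other lists did not pass. Of the chondrocyte-like list, among these, 1 member passed when adjusted over the list alone, lower in fl/fl donors. The cluster led by Cxcl10 and Iigp1, interferon-induced genes, held 178 of 442 fl/fl and 341 of 621 control CAR-like cells. By donor, in the order 1 to 4, these were 3.03, 75.9, 66.7 and 40.0% in fl/fl and 3.41, 80.1, 57.1 and 52.1% in control. In donors 1 and 2 alone, 5 lists passed, and without 1 donor between 0 and 4.

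In PaS-like cells, 2 fl/fl and 3 control donors had enough cells, and no gene passed edgeR. Prg4 (chromosome 1, 150449412 to 150466165, minus strand), which encodes lubricin, stood at 691 ± 124 CPM in fl/fl and 6499 ± 2450 CPM in control donors (SD, n = 2 and 3; log2 difference -3.24, SE 0.454, edgeR adjusted p = 0.869, DESeq2 call). Cpe, a prohormone-processing enzyme gene, stood at 33.9 ± 14.7 and 204 ± 78.9 CPM (log2 -2.45, SE 0.459), and F13a1, a clotting factor gene, at 8.15 ± 1.26 and 78.2 ± 73.7 CPM (log2 -3.36, SE 0.780). Fst, which encodes the activin-binding follistatin, stood at 508 ± 274 CPM in fl/fl and 147 ± 20.4 CPM in control (log2 1.76, SE 0.395), and Phex, a gene of phosphate balance in bone, at 72.7 ± 27.6 and 10.4 ± 10.4 CPM (log2 2.47, SE 0.570). Each had its direction in 2 of 2 fl/fl donors, and apart from Prg4 the adjusted p was 1. Of 7871 genes edgeR called 0, with 87 at an unadjusted p under 0.05; limma-voom called 0, DESeq2 called 1, Prg4, and edgeR without a filter on low counts called 21. The replicate block over donors 1 and 2 called 15, 4 higher and 11 lower in fl/fl. Among them were all 5 genes named here. Their edgeR adjusted p were 5.59e-07 for Prg4, 0.00139 for Cpe, 0.000565 for F13a1, 0.0342 for Fst and 0.0146 for Phex. The same 4 sums without the block called 0 of 8780 genes. With 4 sums the block leaves little from which to estimate the spread of a gene, so these p-values are weak support. On donors 2 to 4 alone, with a single fl/fl sum, edgeR called 9 genes, Prg4 among them.

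Of 25 lists in PaS-like cells, 8 passed camera with the preset correlation. Higher in fl/fl donors were the ribosomal proteins (adjusted p = 1.89e-12), with 74 of 79 members above 0, such as Rps19 (log2 0.51, SE 0.286) and Rps27a (0.49, SE 0.288). The immediate early list (0.000999; 20 of 26 above 0), with Ier3 (0.81, SE 0.370) and Gadd45b (0.58, SE 0.304), the PaS-like list (0.00159; 13 of 18), with Fndc1 (0.83, SE 0.348) and Dpt (0.67, SE 0.310), and the MHC class I list (0.0172; 9 of 11), with Psmb10 (0.77, SE 0.356) and Tap1 (0.97, SE 0.742), went the same way. Lower were the mature blood lineage list (2.81e-06; 0 of 7 above 0), with the globin gene Hbb-bs (log2 -2.41, SE 0.904) and Camp (-2.07, SE 1.502), the blood cell-like list (0.000815), which shares Camp and Hba-a1 (-1.31, SE 0.822), and, of bone and matrix genes, the extracellular matrix list (0.0172), with Fn1 (-0.97, SE 0.394) and Tnc (-1.15, SE 0.542), and the osteoblast-like list (0.0189), with Spp1 (-1.51, SE 0.543) and Col1a1 (-0.61, SE 0.295). With at least 2000 transcripts per cell, which left 4 of the 5 sums, Spp1 turned to 1.31 and Tnc to 0.27. The donors thus changed together with the cell minimum. With an estimated correlation the adjusted p of the 8 lists ran from 0.541 to 0.614, and with fry from 0.0972 to 0.756, so none passed either. No member of these 8 lists passed over all genes, or when adjusted over the list alone. Of lists that did not pass, 1 member of the osteogenic list (camera adjusted p = 0.291) passed over the list alone, higher in fl/fl donors. So did 1 member of the chondrocyte-like list, lower in fl/fl donors. The CAR-like (0.0883), niche factor (0.301), interferon (0.326) and other lists did not pass; the chondrocyte-like list had a median of 0.47, a mean of -0.14 and a downward test (0.859). Control donor 4 gave only 10 cells, and between 4 and 10 lists passed without 1 donor.

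**Figure D2:**
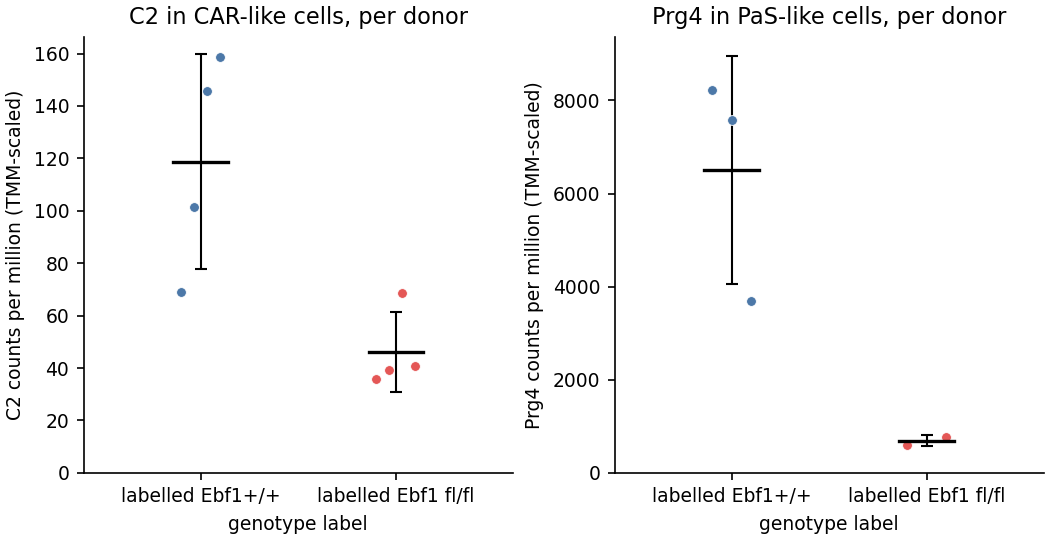
TMM-scaled CPM (y axes, from 0) of C2 in CAR-like and Prg4 in PaS-like cells by genotype label (x axes); points are donors, black lines means and bars SD. Prg4 averages 691 in 2 fl/fl and 6499 in 3 control donors.

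All stromal cells outside blood-like clusters were compared without splitting them by class, and no gene passed. These cells include the unnamed clusters, which are rich in predicted genes. Unnamed clusters held 14.6 to 53.9% of the stromal cells of an fl/fl donor and 10.1 to 57.2% of those of a control donor. Pla1a, a phospholipase gene, stood at 25.6 ± 8.68 CPM in fl/fl and 61.2 ± 11.5 CPM in control donors (SD, n = 4 each; log2 difference -1.25, SE 0.284), Igfbp3 at 54.1 ± 10.8 and 98.9 ± 22 CPM (log2 -0.90, SE 0.220), and Pttg1, which encodes securin, at 18.0 ± 2.27 and 40.0 ± 11.9 CPM (log2 -1.13, SE 0.279). The lipid genes Fabp4, at 32.9 ± 11.7 CPM in fl/fl and 10.7 ± 8.60 CPM in control (log2 1.86, SE 0.500), and Scd2, at 78.1 ± 12.5 and 43.2 ± 10.4 CPM (log2 0.81, SE 0.221), had the smallest p in the other direction. Each had its direction in 4 of 4 fl/fl donors, with an adjusted p of 1. Of 9901 genes edgeR called 0, with 115 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0.

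Whether the genotype differed in effect between CAR-like and PaS-like cells was tested on 5 donors with both classes, and 5 of 11175 genes passed. Rgs5, a pericyte gene, averaged 29.6 ± 34.2 CPM in PaS-like and 27.3 ± 8.94 CPM in CAR-like sums (SD, n = 5), and its genotype effect was higher in CAR-like cells by a log2 of 3.48 (SE 0.645, adjusted p = 0.000389). Cdh13, a cadherin gene, differed by 2.21 (SE 0.495, adjusted p = 0.0215), F13a1 by 4.76 (SE 1.08, adjusted p = 0.0249), and the complement gene C4a by -2.18 (SE 0.427, adjusted p = 0.00118). The fifth, the antibody light chain gene Igkc (adjusted p = 5.15e-07), had a count of 0 in both fl/fl PaS-like sums, which allows up to 1.6 CPM. At an unadjusted p under 0.05 edgeR called 348 genes, and DESeq2 called 0. Without control donor 4, which had 10 PaS-like cells, 0 genes passed, 1 without fl/fl donor 1, 15 without fl/fl donor 2 and 10 without control donor 2.

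The share of each stromal class was compared between genotypes. CAR-like cells made up 27.0 ± 12.5% of fl/fl and 32.7 ± 25.2% of control cells (SD, n = 4 each; two-sided exact permutation p = 0.771). PaS-like cells made up 12.3 ± 13.2% and 7.17 ± 7.01% (exact p = 0.514), blood cell-like 16.0 ± 12.7% and 17.3 ± 15.6% (exact p = 0.857), chondrocyte-like 5.32 ± 3.91% and 3.66 ± 2.78% (exact p = 0.514) and osteoblast-like 1.09 ± 1.09% and 0.982 ± 1.55% (exact p = 0.886). After adjustment over classes each exact p was 0.886, and no difference exceeded the spread between donors. Clusters that met no naming rule, rich in predicted genes, held 38.3% of cells in both genotypes. The gate of donors 2 to 4 is not given and can set these shares.

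**Figure D3:**
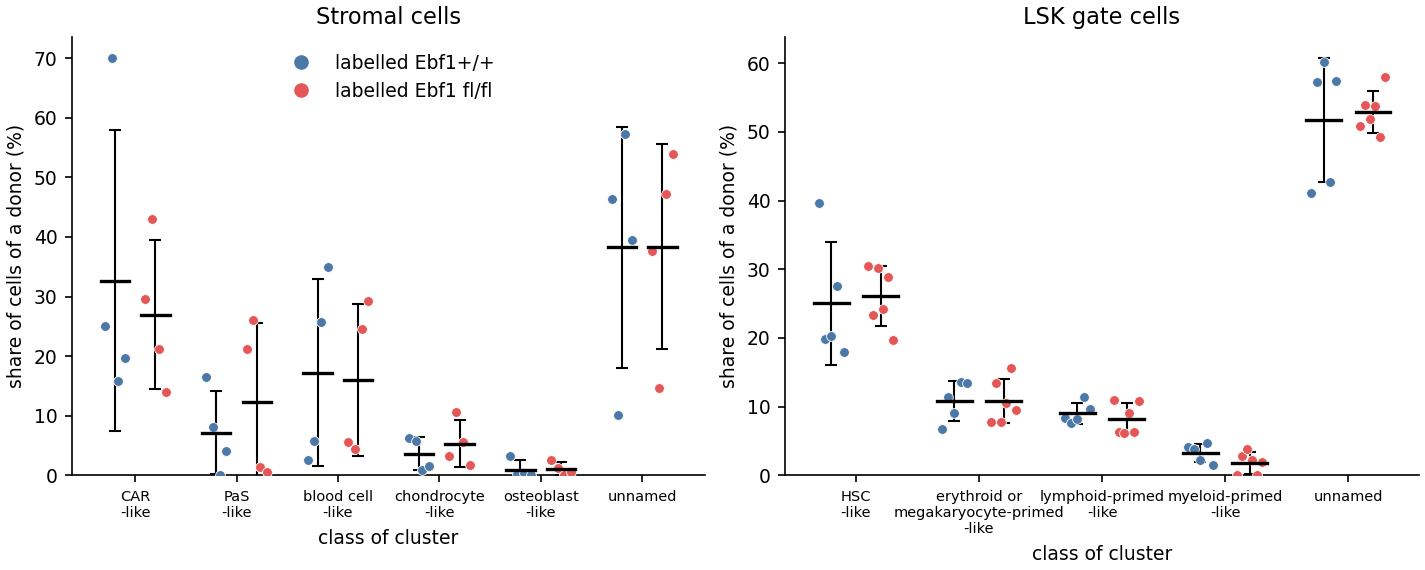
Share of a donor's cells in each class of cluster (y axes, percent) for stromal cells and for LSK gate cells (x axes, classes); points are donors, black lines means and bars SD. Myeloid-primed-like cells average 1.82% of fl/fl and 3.28% of control LSK cells, with overlapping donors.

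The HSC gate and the whole LSK gate were compared within donors to show what the stem cell gate enriched. HSC gate cells were higher in Sult1a1, a sulfotransferase gene (chromosome 7, 126672865 to 126676432, minus strand), at 172 ± 56.0 CPM against 23.7 ± 11.8 CPM (SD, n = 11; log2 difference 2.90, SE 0.088). Also higher were Sdpr (log2 2.55, SE 0.083), the transglutaminase gene Tgm2 (2.43, SE 0.081), Clca3a1 (2.73, SE 0.101), the growth regulator Mycn (1.91, SE 0.076), Mmrn1 (2.07, SE 0.084), Clec1a (2.45, SE 0.099) and Mllt3 (1.87, SE 0.076), a gene of stem cell maintenance. Lower were Plac8 (chromosome 5, 100553725 to 100572245, minus strand), at 33.7 ± 10.5 CPM against 702 ± 152 CPM (log2 -4.39, SE 0.096, adjusted p = 8.23e-26), the granule protease gene Ctsg (-4.48, SE 0.115), the antibody heavy chain gene Ighm (-5.28, SE 0.145), Cd34 (-2.38, SE 0.067), Cd53 (-2.67, SE 0.079), Satb1 (-3.80, SE 0.114), a chromatin organiser of lymphoid cells, and Cd52 (-4.43, SE 0.136). Each had its direction in 11 of 11 donors. Flt3 (-4.03) encodes CD135, by which the gate was drawn. Of 10797 genes, 2426 rose and 2435 fell in the HSC gate; DESeq2 called 4341.

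**Figure D4:**
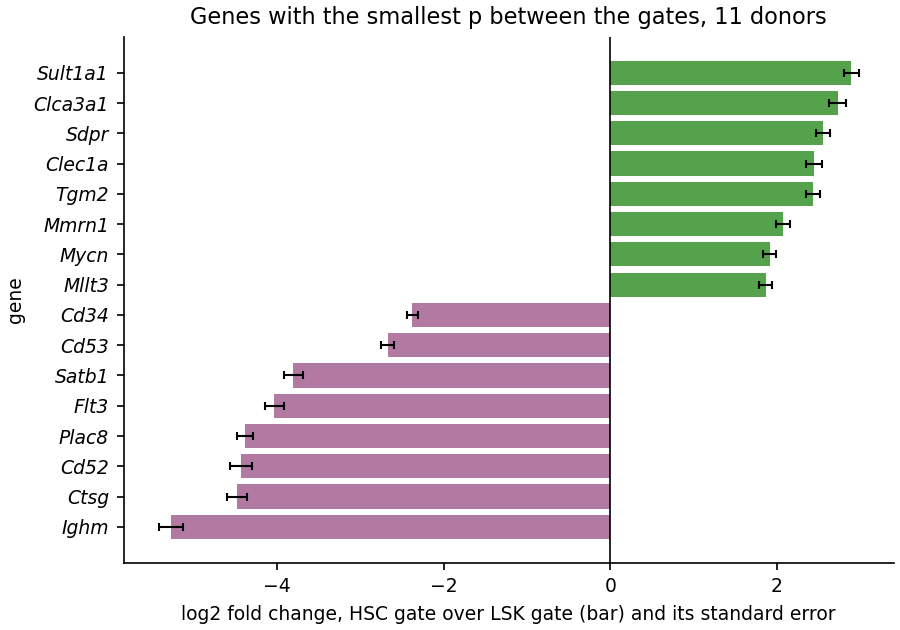
The log2 fold change of the HSC gate over the LSK gate (x axis, bars, with standard errors as thin lines) for the 16 genes with the smallest p each way (y axis), over 11 donors. Values run from -5.28 for Ighm to 2.90 for Sult1a1.

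Of 24 lists, 15 passed camera between both gates, 9 of them also with an estimated correlation, and 21 passed fry. All 24 HSC-like genes rose (adjusted p = 3.37e-28; 0.00472 with an estimated correlation), among them Pdzk1ip1 (log2 1.63, SE 0.075) and Esam (1.48, SE 0.070), as did all 19 of the aged or platelet-biased list (5.33e-22; 0.00472 with an estimated correlation), with Vwf (2.89, SE 0.127) and Clu (2.75, SE 0.125). Of the erythroid or megakaryocyte-primed list 15 rose and 4 fell of 21 (1.60e-06; 0.0258 estimated), with Mpl up (1.53, SE 0.077) and Car1 down (-4.74, SE 0.294). Of the myeloid-primed list 18 of 19 fell (1.87e-18; 0.00710 estimated), with Mpo (-4.64, SE 0.147) and Elane (-4.70, SE 0.211), and of the lymphoid-primed list 16 fell and 3 rose of 19 (7.17e-12; 0.00710 estimated). In the mature blood lineage list 5 of 7 fell (0.0135 estimated), with Cpa3 (-2.95, SE 0.209), and in the blood cell-like list 7 fell and 2 rose of 13 (0.0468 estimated). The endothelial-like list had 6 up and 2 down (0.0258 estimated), with Cldn5 (3.56, SE 0.235), and the niche factors 7 up and 2 down (0.0399 estimated), with Bmp4 (2.73, SE 0.158). Cell cycle genes were lower: 21 of 23 S phase genes fell, such as Mcm5 (-0.88, SE 0.077), and 23 of 24 G2 and M phase genes, such as Top2a (-0.77, SE 0.113), but with an estimated correlation their adjusted p were 0.0914 and 0.296. Oxidative phosphorylation (20 of 30 fell, with Ndufa4 at -0.89, SE 0.067), interferon response (13 rose, with Iigp1 at 1.59, SE 0.146), extracellular matrix (3 rose, with Col1a2 at 2.18, SE 0.215) and immediate early genes (11 rose, with Egr1 at 1.22, SE 0.099) also lost the call, at 0.284, 0.275, 0.0746 and 0.342. Among the lists that passed, counts adjusted over the list alone matched those over all genes except 22 down for S phase, 21 down for oxidative phosphorylation and 4 up for the matrix list. The glycolysis, adhesion and homing, ribosomal, B lineage, CAR-like, adipogenic, sex-linked, MHC class I and PaS-like lists did not pass (adjusted p from 0.222 to 0.984).

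In HSC gate cells, where Ebf1 was near 0, 6 fl/fl and 5 control donors were compared to ask whether the marrow of fl/fl mice left a trace in stem cells. The 1 call was Gm42418, an rRNA-like predicted RNA (chromosome 17, 39846958 to 39848788, plus strand), at 5330 ± 919 CPM in fl/fl and 8388 ± 1840 CPM in control donors (log2 difference -0.66, SE 0.113, adjusted p = 0.0348), lower in 6 of 6; reads of such repeats can come from near-identical copies. It was named after its values were seen. The other genes did not pass: Rif1, which controls replication timing, stood at 140 ± 15.5 and 179 ± 11.6 CPM (log2 -0.36, SE 0.091), the mitochondrial rRNA mt-Rnr2 at 41000 ± 2650 and 49290 ± 5670 CPM (-0.27, SE 0.070), the linker histone gene Hist1h1e at 73.6 ± 14.4 and 103 ± 22.6 CPM (-0.51, SE 0.140), and the helicase gene Ddx41 at 23.5 ± 3.6 and 14.6 ± 1.99 CPM (0.70, SE 0.188), each in 6 of 6 fl/fl donors. Stat1, the interferon signal transducer, stood at 107 ± 27.3 and 75.5 ± 7.27 CPM (0.48, SE 0.133, 5 of 6), with an adjusted p of 0.999 for each of the 5. Of 10142 genes, edgeR called 1, with 473 at an unadjusted p under 0.05; limma-voom called 1 and DESeq2 0 (adjusted p of Gm42418 0.996). Within index set B, Gm42418 was at a log2 of -0.31 (adjusted p = 1) and 0 genes were called, and 29 within index set A. In set A genotype cannot be told apart from library layout. The call was lost without fl/fl donor 1, 2, 3, 4 or 5 or control donor 1 or 4, one at a time, though the log2 difference stayed between -0.67 and -0.56, and it was -0.66 with DESeq2.

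Of 22 lists in the HSC gate, 4 passed camera with the preset correlation, all higher in fl/fl donors. The interferon response list (adjusted p = 0.00556) had 18 of 22 members above 0, such as Igtp (log2 0.51, SE 0.176) and Zbp1 (0.65, SE 0.264), the ribosomal proteins (0.00903) 71 of 85, such as Rplp2 (0.30, SE 0.130), oxidative phosphorylation (0.0173) 28 of 30, such as Uqcrh (0.19, SE 0.085), and MHC class I (0.0439) 12 of 12, such as Psmb8 (0.17, SE 0.098). With an estimated correlation each adjusted p was 0.904, and with fry 0.940. No member passed over all genes; adjusted over the list alone, 1 interferon gene did. The HSC-like (0.188), aged or platelet-biased (0.161), lymphoid-primed (0.795), myeloid-primed (0.857), S phase (0.124) and other lists did not pass. Within index set A, 2 lists passed as higher and 1 as lower, and within set B 3 and 1; without 1 donor between 1 and 7 passed. Under the replicate block, which also leaves out fl/fl donor 6, no list was higher and 1 was lower. Leaving out that donor alone, without the block, gave the same counts.

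In LSK gate cells the same donors were compared, and no gene passed. Higher in fl/fl donors were Mrrf, a mitochondrial ribosome recycling factor gene, at 42.3 ± 4.88 and 29.6 ± 4.02 CPM (SD, n = 6 and 5; log2 0.52, SE 0.134), Dpagt1, of N-glycan synthesis, at 35.9 ± 2.50 and 26.2 ± 2.96 CPM (0.45, SE 0.131), Naprt, of NAD synthesis, at 24.6 ± 4.13 and 15.3 ± 5.17 CPM (0.70, SE 0.210), and Usp53 at 14.95 ± 2.57 and 8.82 ± 1.47 CPM (0.72, SE 0.217). Atad5, a replication gene, stood at 55.1 ± 8.56 in fl/fl and 73.6 ± 7.58 CPM in control (-0.42, SE 0.117), and Gm42418 at 5175 ± 1190 and 6735 ± 668 CPM (-0.38, SE 0.126). Each held in 6 of 6 fl/fl donors with an adjusted p of 1. Of 10167 genes edgeR called 0, with 308 at an unadjusted p under 0.05; DESeq2 and limma-voom called 0. Within index set A, 6 genes fell (Elane, Ly6c2, Hp, Fcgr3, Ms4a3 and Igsf6), of which Ly6c2 was at a log2 of 0.30 and Igsf6 at 0.24 within set B, where 23 genes rose, mostly predicted genes, the satellite-like ones among them.

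Of 24 lists in the LSK gate, 3 passed camera with the preset correlation, all lower in fl/fl donors. The myeloid-primed list (adjusted p = 0.000237) had 4 of 18 members above 0, with Clec12a at a log2 of -0.55 (SE 0.200), Igsf6 at -0.82 (SE 0.341), Prtn3 at -0.33 (SE 0.190) and Ly6c2 at -0.76 (SE 0.547). The lymphoid-primed list (0.0295) had 5 of 20 above 0, with Dntt, which diversifies antigen receptors, at -0.47 (SE 0.224) and Ighm at -0.26 (SE 0.128), and the ribosomal proteins (0.000237) 14 of 85, with Rpl10 at -0.35 (SE 0.180). With an estimated correlation their adjusted p were 0.840, 0.840 and 0.844, and with fry 0.985. No member passed over all genes or when adjusted over the list alone. The HSC-like (0.287), erythroid or megakaryocyte-primed (0.987), B lineage (0.365), interferon (0.160), immediate early (0.160) and other lists did not pass. Within index set A, 2 lists passed as higher and 3 as lower, within set B 3 and 2, and under the replicate block 2 and 4. The block also leaves out fl/fl donor 6, and without that donor alone 2 lists were higher and 3 lower.

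**Figure D5:**
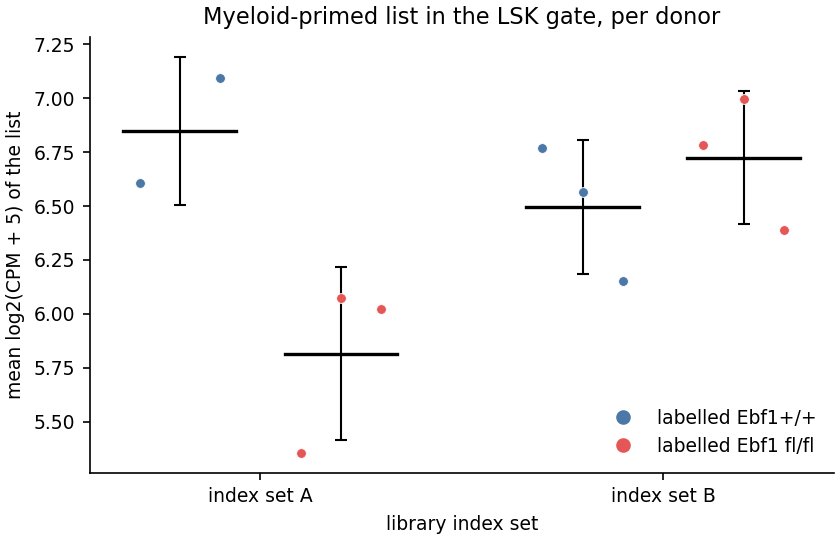
Mean log2 of CPM plus 5 over the 18 measured genes of the myeloid-primed list (y axis) in LSK gate cells of each donor, by inferred library index set (x axis); points are donors, black lines means and bars SD. The fl/fl donors lie below the control donors in set A and not in set B. In set A the library layout also went with genotype.

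Whether the genotype differed in effect between HSC and LSK gates was tested over the 11 donors, and no gene passed. The smallest p belonged to Trp53cor1, the p53-induced lincRNA gene (log2 difference of effects 1.41, SE 0.376), the cullin gene Cul5 (-0.70, SE 0.189), Ptn, which encodes pleiotrophin (-1.73, SE 0.510), the endosome gene Eea1 (-0.61, SE 0.181) and the stress kinase gene Mapkapk2 (0.42, SE 0.128), each with an adjusted p of 1. Of 10797 genes edgeR called 0, with 397 at an unadjusted p under 0.05, and DESeq2 called 0.

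Cell classes within the LSK gate were compared between genotypes. Myeloid-primed-like cells made up 1.82 ± 1.56% of fl/fl and 3.28 ± 1.35% of control cells (SD, n = 6 and 5; two-sided exact permutation p = 0.145, adjusted 0.580). Within index set A the shares were 0.758% and 4.43% (exact p = 0.200) and within set B 2.87% and 2.52% (exact p = 0.700). HSC-like cells made up 26.2 ± 4.36% and 25.0 ± 8.92% (exact p = 0.810), lymphoid-primed-like 8.28 ± 2.29% and 9.08 ± 1.53% (exact p = 0.515), and erythroid or megakaryocyte-primed-like 10.8 ± 3.17% and 10.8 ± 2.93% (exact p = 0.983). None passed after adjustment at clustering resolution 1. At resolution 0.5 the class named myeloid-primed-like passed with 13.0 ± 1.73% of fl/fl and 19.0 ± 1.95% of control cells (exact permutation p = 0.0022, adjusted 0.0065). Of its 255 cells only 42 were so named at resolution 1, while 104 were lymphoid-primed-like and 109 unnamed. Its lower share is thus not that of the myeloid-primed-like class of resolution 1. At resolution 1, 52.9% of fl/fl and 51.7% of control cells stayed unnamed.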

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

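Of the tests below, those with cells thinned and with low-quality cells left out were set before their result was seen; all others, the splits included, were chosen after. For the thinned cells, the low-quality cells and the index sets, the requirement that a value pass its bound by more than its standard error was also added after the values were known. The tests with the index set as a covariate replaced tests within each set, which had left the satellite-like genes open and had gone with a batch for the myeloid-primed list. The draws for Prg4 were likewise revised to redraw cells; an earlier form without this left the Prg4 test undecided.

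Of 78 groups of 4 to 10 donors, 4 held a value far from the others, and chance alone marks about 1 in 20 groups. C2 stood at 68.7 CPM in CAR-like cells of fl/fl donor 3 and at 35.7 to 41.0 CPM in the other fl/fl donors. Ebf1 stood at 774 CPM in all stroma of control donor 3 after scaling, against 512 to 552 CPM in the others; without scaling it was the lowest at 457 CPM and control donor 2 stood apart at 761 CPM, so the scaling made this value. Osteoblast-like cells made up 3.29% of control donor 1 and 0 to 0.450% of the other control donors. Mitochondrial transcripts made up 12.4% in HSC gate cells of control donor 5, against 13.4 to 13.8%.

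For 5 genes the genotype effect in CAR-like cells differed from that in PaS-like cells by the interaction test. These were Igkc, with a fitted log2 difference of 8.70 that is no bound since its count in fl/fl PaS-like cells was 0, Rgs5 (3.48), Cdh13 (2.21), F13a1 (4.76) and C4a (-2.18). Igkc was also among the 10 leading genes of a blood cell-like stromal cluster. F13a1 was among those of the myeloid-primed-like cluster of the LSK gate. Without control donor 4, whose PaS-like sum held 10 cells, 0 genes were called.

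Outside the measurement itself, spike-in transcripts reached 23.1% of a library in stromal donor 2, where they made up 15.1 to 23.1% in fl/fl and 5.09 to 19.2% in control libraries; elsewhere they stayed at or under 0.571%. Barcodes outside the filled blocks with at least 1000 transcripts numbered 59 in HSC libraries, 28 of them in control donor 3, 67 in LSK libraries, 30 of them in fl/fl donor 6, and 1 in stromal libraries.

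The myeloid-primed list was lower in LSK cells of fl/fl donors by a mean log2 of -0.37 over 18 genes (exact permutation p = 0.255, n = 6 and 5), though camera passed it with the preset correlation; with an estimated correlation (adjusted p = 0.840) and with fry (0.985) it did not pass. The difference was -1.03 within index set A (exact p = 0.1, the smallest possible for 3 against 2) and 0.229 within set B (SE 0.254, exact p = 0.4). Both sets hold both genotypes, and with the set as a covariate it was -0.333 (SE 0.296, exact p = 0.31 over relabelling within sets) and camera with the preset correlation gave an adjusted p of 0.0221. Genotypes are spread nearly evenly over the sets, so the covariate can move the difference little, and the exact p does not set it apart from 0. A shift between the sets as its cause is thus not decided, and why the sets differ in direction stays open. Within set A genotype also went with library layout, 2 libraries of 96 filled barcodes in control donors and 1 of 128 in fl/fl donors. The difference within set A cannot be told apart from this layout. With each cell thinned to 1000 identifiers the difference was -0.291 (SE 0.217). This standard error is too wide to tell a few deep cells apart from the rest as its source. At clustering resolution 0.5 a wider cluster held 13.0% of fl/fl and 19.0% of control cells. Its share was lower in every fl/fl donor than in every control donor, in both sets. Of its 255 cells, 42 were myeloid-primed-like at resolution 1, 104 lymphoid-primed-like and 109 unnamed. An effect of the genotype in part of the donors stays open and untested.

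Satellite-like predicted genes, 7 in number, made up 10.3 ± 2.24% of HSC gate transcripts in fl/fl and 7.82 ± 1.97% in control donors (exact permutation p = 0.0931, n = 6 and 5), and 5.06 ± 1.35% against 3.32 ± 1.31% in the LSK gate (exact p = 0.0649). With only cells of at least 2000 genes, 1346 of 1524, the HSC gate difference was 2.401 percentage points against 2.50 over all cells. It passed the bound set for it by 1.15 points (SE 0.638). Shares are weighted by transcripts, so the few cells left out could carry little of the difference. The test shows that it was also present in cells with at least 2000 genes, not that cell quality plays no part. In the HSC gate the difference was 4.39 points within index set A (exact p = 0.1) and 1.197 within set B (SE 1.71, exact p = 0.6). In the LSK gate it was 0.784 within set A (SE 1.25, exact p = 0.9) and 2.29 within set B (SE 0.673, exact p = 0.1, the smallest possible for 3 against 3). With the set as a covariate the differences were 2.618 (SE 1.31, exact p = 0.075) in the HSC gate and 1.623 (SE 0.766, exact p = 0.085) in the LSK gate. They nearly kept their size, but genotypes are spread nearly evenly over the sets and neither exact p was under 0.05. A shift between the sets as their cause is thus not decided. Differences within set A also cannot be told apart from the library layout, which there went with genotype. Reads of these repeats may also come from near-identical copies, which was not tested, and a biological difference stays open.

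Prg4 was lower in PaS-like cells of fl/fl donors, and 46 cells with at least 20 Prg4 transcripts held 93.2% of it. They made up 20.9%, 14.3% and 10.0% of PaS-like cells in control donors 1, 2 and 4 and 6.34% and 5.71% in fl/fl donors 1 and 2. Such a cell held on average 55.4 and 55.0 Prg4 transcripts in fl/fl donors 1 and 2 and 283 and 353 in control donors 1 and 2, so their lower share alone leaves part of the difference; 1 cell held 57.2% of the Prg4 of control donor 1. Among the other PaS-like cells the ratio of control to fl/fl was 1.25, whereas a loss alike in every control cell gave a median of 3.13, and 1.25 or less in 22 of 1000 draws of cells. The CPM in these other cells were 208 and 194 in fl/fl donors 1 and 2 and 416, 289 and 50.1 in control donors 1, 2 and 4. Without control donor 4, which had 10 cells, the ratio was 1.75, against a median of 2.98 and 47 of 1000 draws as low. A loss among the richest cells, such as those of the joint surface, could account for the difference. The draws take cells anew within control donors and leave out the spread between donors, so they do not exclude an even loss. Low counts in the other cells may in part be carried over between wells, which was not tested. PaS-like cells of donor 1 came from the labelled PaS gate in both genotypes, while the gate of donors 2 and 4 is not given. The control to fl/fl ratio of Prg4 CPM over all PaS-like cells was at least 10.23 in both donor pairs. Prg4 was picked for its difference in these same sums, so this cannot decide on a batch of 1 pair. Whether the genotype, a batch or the sampling of cells changed Prg4 stays open.

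Other splits of the same donors were fitted to see whether chance can be excluded. For HSC against LSK it can: 1 of 100 splits, the real one with 4861 genes, gave as many, and the highest other gave 1. For the genotype in the HSC gate it cannot, since 21 of 100 splits gave at least the real 1 call and the highest other 20. The real count was 0 in the LSK gate, the progenitor interaction, CAR-like cells and all stroma, so all 100, 100, 35 and 35 splits gave as many, with highest other counts of 21, 21, 193 and 547. The counts of 193 and 547 came from the split of fl/fl donors 1 and 4 with control donors 1 and 3 against the rest. It was picked as the highest of the splits, so whether it reflects a structure of the donors was not tested. Parting donors 1 and 2 from donors 3 and 4 gave 5 and 85. In all stroma the replicate block, which takes the donor numbers into account, also called 0. PaS-like cells and the stromal interaction, with 2 fl/fl and 3 control donors, were not split this way.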

How the results depend on the processing

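Alternatives added after seeing the data were sums without predicted genes, filled barcodes alone, cells with at least 1000 genes, stromal donors 1 and 2 alone, lists within index sets or between the HSC and LSK gates, the replicate block with an estimated correlation, shares of named cells or within index sets, and leaving out donors in the HSC against LSK and interaction tests; the others were set before. Of counts of calls, 116 stayed within 1.5 times under these settings and 37 moved; when 1 donor was left out, 109 stayed and 26 moved. Of named genes, 2118 values kept direction and side of the threshold, 21 newly passed, 16 lost a call and 16 reversed; with 1 donor left out these were 1753, 3, 24 and 2. Where no construction is named, the cause was not tested. The counts for CAR-like cells and all stroma stayed at 0 in every setting run. The gate counts between HSC and LSK stayed between 4341 and 5500, and 4467 to 4792 without 1 donor. DESeq2 moved the median log2 of all genes to 0.18 between the HSC and LSK gates and to 0.19 in the stromal interaction.

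Without a filter on low counts, which tests more genes, calls numbered 21 in PaS-like cells, 21 in the HSC gate, 56 in the LSK gate and 13 in the progenitor interaction. In PaS-like cells donors 2 to 4 alone, with a lone fl/fl sum whose spread was taken from the control sums, gave 9, among them Prg4 at -2.84 (edgeR adjusted p = 0.0273) and F13a1 at -3.60. DESeq2 called 1 in PaS-like cells, 0 in the HSC gate and 0 in the stromal interaction, where 2000 transcripts per cell gave 0 and 500 gave 9 on fewer sums. In the HSC gate thinned cells gave 4, sums without predicted genes 0, which removes the called gene itself, index set A 29 and index set B 0. In the LSK gate index set A gave 6 and index set B 23. Without 1 donor, calls ran from 0 to 1 in the HSC gate and 0 to 15 in the stromal interaction. Of LSK classes 1 passed at clustering resolution 0.5, the myeloid-primed-like one with 13.0 ± 1.73% of fl/fl and 19.0 ± 1.95% of control cells (exact permutation p = 0.0022, n = 6 and 5), which there took in many lymphoid-primed-like and unnamed cells.

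CAR-like sums did not meet the rule for pairing, as same-numbered correlations were 0.618, 0.364, 0.065 and 0.113 for numbers 1 to 4. Numbers 1 and 2 still went together, and the main CAR-like fit leaves this spread in. With the block 321 CAR-like genes had an edgeR p under 0.05, against 143 without it, and 0 passed in either. PaS-like sums had only 2 pairs. The HSC and LSK gates did not pair by number either, since not every correlation was over 0.1. With the replicate block, calls numbered 15 in PaS-like cells and 2 in the HSC gate, and lists 1 in the HSC gate and 6 in the LSK gate. The block also leaves out unpaired donors. In PaS-like cells the same 4 sums without the block called 0. Without fl/fl donor 6 alone the HSC gate gave 1 call and 1 list, and the LSK gate 5 lists. The block with an estimated correlation gave 0 lists in CAR-like, 0 in PaS-like, 0 in HSC gate and 0 in LSK gate cells. The replicate block moved no other count of calls or lists by over 1.5 times.

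Lists that passed numbered 0 with an estimated correlation and 0 with fry in CAR-like, PaS-like, HSC gate and LSK gate cells, and 9 with an estimated correlation between the HSC and LSK gates. In CAR-like cells donors 1 and 2 alone gave 5, and in the LSK gate index set A gave 5 and index set B 5. Without 1 donor, lists ran from 0 to 4 in CAR-like, 4 to 10 in PaS-like, 1 to 7 in HSC gate and 2 to 7 in LSK gate cells.

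Genes that reversed had not passed. In PaS-like cells, with 2000 transcripts per cell, which left 4 of the 5 sums, Spp1 was at 1.31, Tnc at 0.27 and Col8a1 at 0.72. With 500, which leaves out control donor 4, Col8a1 was at 0.81. Both settings thus changed the donors as well as the cell minimum. Thinned cells put Srgn at -0.17, without fl/fl replicate 1 Srgn was at -0.36 and S100a9 at 0.51 (lowest without 1 donor -3.90), and with donors 2 to 4 alone at -0.77 and 0.31. In the HSC gate, index set B put Uqcr10 at -0.023 and H2-Q4 at -0.048, and thinned cells Cox5a at 0.078 and Rps6kb1 at 0.26. In the LSK gate, index set A put Dntt at 0.11, index set B put Igsf6 at 0.24, Prtn3 at 0.093 and Ly6c2 at 0.30, and thinned cells Ighm at 0.032. Other rRNA-like and satellite-like genes of the progenitors, near 0 in the LSK gate, were looked at and left out of these counts after their values were seen.

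Not run was leaving out cells with over 2% of transcripts from Kcnq1ot1, since 0 cells exceeded it. In simulated data 22 of 100 genes changed 4-fold were found in PaS-like cells with 5 sums, against 100 in the HSC gate with 11; depth, spread and number of sums differ between them.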

Other observations

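CAR-like cells of donor 1 lay mainly in a cluster of 374 cells and those of donor 2 in a cluster of 519 cells led by Cxcl10, Iigp1 and Cxcl9, all interferon-induced, in both genotypes. A further 160 cells were chondrocyte-like, 80 in each genotype, and 48 osteoblast-like, 23 in fl/fl and 25 in control donors. Bglap, the osteocalcin gene, reached 1123 CPM in the CAR gate of fl/fl donor 1 and 205 CPM in that of control donor 1, with 21.99 and 121 CPM in the PaS gates; with 1 donor each this was not tested.

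Predicted satellite-like genes took 57.2% of the transcripts of stromal barcodes with at least 1000 transcripts but under 500 genes, and 16.4% in those with at least 1000 of both. In Prg4-poor PaS-like cells Ebf1 stood at 1190 and 1045 CPM in fl/fl donors 1 and 2, and at 567, 617 and 468 CPM in control donors 1, 2 and 4.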
